A study of Homo sapiens with 18 samples.

How the data were processed

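Gene expression was measured on 18 Affymetrix Human Gene 2.1 ST arrays, per the series' design text, in HEK293 cells that overexpress murine TLR5. Per the labels' protocols, the cells grew in media with heavy, medium or light lysine and arginine, reached passage 7, and were stimulated in flasks. The flagellin dose was set to match a multiplicity of infection of 10, and 100 ng of total RNA went into each labelling reaction. Which array had which amino acid label, and the day of each culture and hybridisation, are not given in the sources used here. The groups were mock, EcN flagellin and ST flagellin, each at 60 and 120 min, with 3 arrays per group lettered A, B and C. The labels conflict for the 6 ST arrays: their titles, source names and treatment fields name ST flagellin, and their description fields name mock. The titles were followed.

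The deposited values are on a log2 scale. They come from RMA in the R package oligo 1.30.0, per the submitters' processing notes, which name no annotation version or further setting. The table holds 53617 rows, each a transcript cluster of the array, and values from 0.17 to 13.62. Array medians over all rows lay between 2.27 and 2.32. The values were used as deposited, with no further normalization. Rows were named through the platform's annotation. Of the rows, 23871 had 1 gene symbol, 1842 had several, and 27904 were not listed there and are unnamed here. Gene symbols were brought up to date through Entrez gene identifiers and older symbols in the RefSeq gene table of the GRCh38.p14 assembly, used for names alone. This changed 655 symbols, and 4 rows kept the platform's own. No coordinates are given, since the sources used here name no genome build for the array.

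Rows with 1 symbol were kept if they lay above their own array's median on at least 3 of the 18 arrays. The row with the highest mean over all arrays then stood for its gene, which affected 399 genes with several such rows. This left 16111 genes. Rows with no symbol or several symbols were tested apart and enter no named result.

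Differences were tested with limma 3.58.1 in R 4.3.3. The linear model (lmFit) had 6 group means and took all 18 arrays, so that the groups shared 1 estimate of the spread per gene, with 12 residual degrees of freedom and 4.20 from the prior (eBayes, default settings). There were 11 comparisons: each flagellin over mock at each time, ST over EcN at each time, the mean of both flagellins over mock at each time, the change of each flagellin's effect from 60 to 120 min, and mock 120 min over mock 60 min. All p-values are two-sided and were adjusted by the Benjamini-Hochberg method over the genes tested within a comparison, with a gene called at an adjusted p under 0.05. The design, the alternatives, the gene lists and the rule for named genes were fixed before the data were examined.

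Named genes were chosen by rule. Against mock they were the 15 called genes with the highest and the 10 with the lowest log2 fold change, or 10 and 10 in the other comparisons. Where no gene was called they were the 5 with the smallest p. To these came up to 4 members of each list by absolute log2 fold change, and TLR5, NFKBIA, TNFAIP3, CXCL8, JUN, EGR1, ACTB and GAPDH in every comparison with mock. Any other gene named is a called member of a list or comes from a count of called members.

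The 22 gene lists were TLR5-MyD88 signalling, NF-kB subunits and feedback inhibitors, cytokines and chemokines, other NF-kB targets, immediate-early genes, MAP kinase feedback inhibitors, interferon-stimulated genes, NAIP-NLRC4 and inflammasome genes, the unfolded protein response with ATF4 targets, heat shock proteins, cholesterol synthesis with SREBP targets, cell cycle, hypoxia and glycolysis, p53 targets, and TGF-beta and BMP feedback. Leukocyte, fibroblast and intestinal epithelium markers stood for other cell types. Cytosolic ribosomal proteins, housekeeping genes, small nucleolar with Cajal and spliceosomal RNAs, and microRNA precursors stood for RNA quality. A list with at least 5 measured members was tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the 20 such lists within a comparison. The same test with an estimated correlation, and limma's fry, stood beside it. Of the 220 list tests, 52 passed with the preset correlation and 3 with the estimated one, all 3 of them p53 targets.

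The overlap of both flagellins' effects was set against 100 simulations of unchanged groups that share the same mock arrays. The simulations used the pooled spread of each gene, and the values expected from each group's own spread were added after seeing the data. The 3 mock arrays of a time are too few to split. The fit was tested on simulated data for the comparison of ST with mock at 60 min, over 5 runs on 16111 genes. Each gene kept its measured mean and residual SD, with independent normal noise and no correlation between genes. It recovered 46.3% of genes changed 1.5-fold, 88.4% of those changed 2-fold and 99.4% of those changed 4-fold, with 6.37% false calls, and it made 0 calls when nothing was changed.

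The alternatives were a fit of the compared groups alone, the replicate letter as a block or as a random block, eBayes with trend and robust settings, no filter or a stricter filter on dim rows, the mean of a gene's rows, renewed quantile normalization, centring of each array on its median, array weights, a 1.5-fold minimum, and leaving out each array in turn. Leaving out all arrays lettered C, alone or together with mock 120 min A, was added after seeing the data. Camera takes no random block, so with that block the lists were tested on the moderated statistics of the fit (cameraPR), and camera has no robust setting, so there the trend alone was used. Tables were prepared with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.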

Results

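Transcript levels were measured in HEK293 cells, a human embryonic kidney line, that overexpress murine TLR5, the receptor for bacterial flagellin. The cells received no flagellin (mock), flagellin of the probiotic E. coli Nissle (EcN) or flagellin of Salmonella Typhimurium SL1344 (ST). RNA was taken at 60 and 120 min from 3 arrays per group, 18 in all, and 16111 genes were tested. The labels call the replicates A, B and C biological, and whether a letter stands for a separate culture is not given in the sources used here. The number of arrays limits the precision: in simulated data with 3 arrays per group, 46.3% of genes changed 1.5-fold were called and 88.4% of those changed 2-fold. Changes are given as log2 fold changes with their SE from the limma fit unless a level is named. Against mock, rose and fell mean higher and lower than in mock and name no cause. The amino acid label of each array is not given, so a difference between labelled cultures cannot be told apart from flagellin.

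The NF-kB response, the best known outcome of TLR5 signalling, appeared on 5 arrays that did not follow the groups of the labels. NFKBIA (transcript cluster 16791991), which encodes the inhibitor of NF-kB that NF-kB itself induces, had a log2 level of 10.15 on EcN 60 min C, 10.34 on EcN 120 min C, 10.85 on ST 60 min C and 10.64 on ST 120 min C. It was as high, at 10.83, on the array labelled mock 120 min replicate A, and lay between 8.09 and 8.82 on the other 13 arrays. TNFAIP3 (transcript cluster 17012946), an NF-kB feedback inhibitor, stood at 8.20, 9.27, 9.48 and 9.60 on those 4 flagellin arrays and at 9.27 on mock 120 min A, against 5.95 to 6.55 elsewhere. CXCL8 (transcript cluster 16967771), a neutrophil chemokine, stood at 5.62, 7.47, 7.92, 8.76 and 7.53 in the same order, against 2.16 to 2.90 elsewhere, and TNF at 3.80, 5.69, 5.55, 6.12 and 6.13, against 2.57 to 3.17. The arrays lettered A and B of both flagellins were among these other 13, with the remaining mock arrays, at both times. The groups of the labels were kept, so every comparison below holds arrays that differ in this response, and no member of the list of NF-kB subunits and inhibitors was called in any of them.

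**Figure D1:**
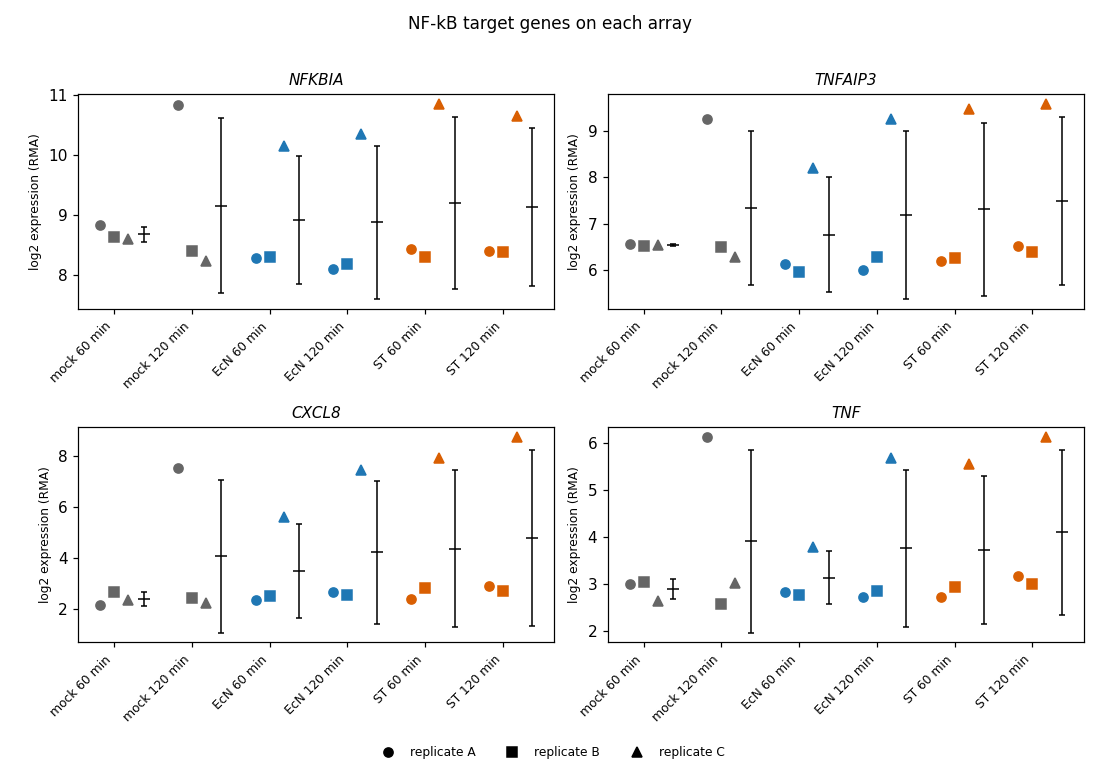
Log2 levels of NFKBIA, TNFAIP3, CXCL8 and TNF by group, with a point per array, a horizontal mark at the mean of 3 arrays and whiskers of 1 SD. NFKBIA lies between 10.15 and 10.85 on mock 120 min A and on the 4 flagellin arrays lettered C, and between 8.09 and 8.82 on the other 13.

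The first question was which transcripts differ from mock after 60 min with EcN flagellin. Interferon-stimulated genes, which encode antiviral proteins, rose most: IFI44L (transcript cluster 16666485) by 2.86 ± 0.53 (7.28-fold), IFIT3 by 2.55 ± 0.57, the antiviral synthetase OAS2 by 2.07 ± 0.38 (4.20-fold) and the ubiquitin-like ISG15 (transcript cluster 16657594) by 1.92 ± 0.41 (3.80-fold). The immediate-early transcription factors EGR1 (transcript cluster 16989736), FOS and EGR3 rose by 1.83 ± 0.37, 1.45 ± 0.38 and 1.21 ± 0.33. Without flagellin, EGR1 and EGR3 also stood higher in mock at 120 min. Their levels there were 9.80 to 10.99 and 5.51 to 6.53, against 8.89 to 9.27 and 4.52 to 5.25 in mock at 60 min. INSIG1, the sterol sensor that holds back SREBP, rose by 1.07 ± 0.17 (2.10-fold). GALR2, a galanin receptor, fell by 1.62 ± 0.22 on the log2 scale (3.07-fold) and SETD1B, a histone methyltransferase, by 1.13 ± 0.19. SMAD7, an inhibitor of TGF-beta signalling, fell by 1.02 ± 0.21 and the histone gene H2BC14 by 1.24 ± 0.32. In all 496 genes were higher and 543 lower with EcN, or 402 and 727 after each array was centred on its median. Of these 1039, 494 changed at least 1.5-fold. The adjusted p was 0.0186 for IFI44L, 0.0199 for ISG15, 0.0195 for EGR1, 0.0159 for INSIG1 and 0.00877 for GALR2.

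By list, 13 of 20 interferon-stimulated genes rose with EcN at 60 min and 0 fell, with 17 higher when adjusted over the list alone, a median of 1.19 and all 20 above 0. The set test gave an adjusted p = 5.72e-13 with the preset correlation and an adjusted p = 0.314 with an estimated correlation. ISG15 levels were 3.17, 3.19 and 3.79 on the mock 60 min arrays and 4.22, 5.91 and 5.79 on the EcN arrays A, B and C. Of 28 immediate-early genes 5 rose (EGR1, FOS, EGR3, IER5 and KLF6), or 8 adjusted over the list alone, and the list did not pass its set test (median 0.29, adjusted p = 0.0775). The SREBP targets INSIG1 and IDI1 were the 2 that rose among 12 cholesterol genes, 3 adjusted over the list alone (median 0.15, adjusted p = 0.0775). In the TLR5-MyD88 list of 18, PELI1, a ubiquitin ligase of the pathway, rose by 0.49 ± 0.13, while IKBKG and the adaptor TIRAP fell by 0.59 ± 0.14 and 0.67 ± 0.16, or 2 higher and 4 lower adjusted over the list alone (median -0.06, adjusted p = 0.326). Human TLR5 itself, which is not the murine transgene, did not pass the test (0.25 ± 0.18, adjusted p = 0.402). Among cytokines, the chemokine CCL5 rose by 0.82 ± 0.18, the 1 member called of 20. Of 20 NF-kB subunits and inhibitors limma called 0, with 0 higher and 2 lower at an unadjusted p under 0.05, and their median of 0.05 was opposite in sign to their set test (downward, adjusted p = 0.723). NFKBIA (0.23 ± 0.85), TNFAIP3 (0.23 ± 1.10) and CXCL8 (1.10 ± 1.85) had standard errors larger than their changes. CD68, the 1 leukocyte marker called of 4, rose by 0.39, and the intestinal marker LGR5 fell by 0.59 ± 0.16. B2M of the housekeeping list and RPS6 of the ribosomal list rose by 0.53 and 0.38 beside these groups.

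The count of 1039 rested on single arrays of both groups: it was 671, 7 and 3 without mock 60 min A, B and C, 241, 0 and 81 without EcN 60 min A, B and C, and 1856 and 1615 without mock 120 min A and C. Without the arrays lettered C it was 14, and without these and mock 120 min A it was 494, both chosen after seeing the data, and with array weights 2176.

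For ST flagellin after 60 min the same question gave a like picture. Interferon-stimulated genes again rose most, IFI44L by 3.59 ± 0.53, IFIT3 by 3.17 ± 0.57 (9.03-fold), ISG15 by 3.13 ± 0.41 (8.74-fold) and OAS1 by 2.53 ± 0.46 (5.77-fold). The RNA sensor RIGI rose by 1.62 ± 0.27 and the interferon signalling factor IRF9 by 1.59 ± 0.21. FOS, EGR1 and EGR3 rose by 1.71 ± 0.38 (3.26-fold), 1.67 ± 0.37 and 1.46 ± 0.33. The p53 targets GDF15, a stress cytokine, and TP53I3 rose by 1.28 ± 0.26 (2.43-fold) and 0.70 ± 0.15, and GADD45A, a growth arrest gene, by 1.03 ± 0.19. The membrane protein gene TMEM47 fell by 1.31 ± 0.20 and the transporter gene SLC10A5 by 1.31 ± 0.26. The histone genes H2BC12 and H2BC14 fell by 1.21 ± 0.26 and 1.19 ± 0.32, and SMAD7 by 0.88 ± 0.21. Of 848 genes called, 360 were higher and 488 lower with ST, and 362 changed at least 1.5-fold. The adjusted p was 0.00551 for IFI44L, 0.00532 for ISG15 and for IRF9, 0.0223 for EGR1 and 0.0164 for GDF15.

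Of the 20 interferon-stimulated genes, 15 rose with ST at 60 min and 0 fell, or 19 adjusted over the list alone, with a median of 1.58 (adjusted p = 1.43e-21, adjusted p = 0.0828 with an estimated correlation). ISG15 levels on the ST arrays were 6.41, 6.50 and 6.62. Of 28 immediate-early genes 6 rose, ATF3 with the 5 called for EcN, and 11 adjusted over the list alone (median 0.49, adjusted p = 8.9e-06, adjusted p = 0.536 with an estimated correlation). The p53 list held both GDF15 and TP53I3 as called, with 5 of 11 adjusted over the list alone (median 0.35, adjusted p = 0.001, adjusted p = 0.0367 with an estimated correlation). Other NF-kB targets had 1 of 16 called, GADD45A, and 1 adjusted over the list alone (median 0.45, adjusted p = 0.0233, adjusted p = 0.536 with an estimated correlation). In the unfolded protein response list XBP1 and PHGDH rose, 2 of 18, or 5 adjusted over the list alone (median 0.21, adjusted p = 0.0155, adjusted p = 0.536 with an estimated correlation). Among cholesterol genes IDI1 and INSIG1 rose by 0.69 ± 0.14 and 0.62 ± 0.17 and SC5D fell by 0.59 ± 0.15. The list's median of -0.04 and mean of 0.05 differed in sign, with an upward test at an adjusted p = 0.858. For NF-kB subunits and inhibitors limma called 0 of 20, with 2 higher and 2 lower at an unadjusted p under 0.05 (median 0.16, adjusted p = 0.852). CXCL8 (1.98 ± 1.85) and NFKBIA (0.52 ± 0.85) did not pass. Other NF-kB targets lost their call without mock 60 min C (adjusted p = 0.0558) or ST 60 min C (adjusted p = 0.268). The unfolded protein response lost its own without the same arrays (adjusted p = 0.0633 and 0.0547). B2M and RPS6 rose by 0.39 and 0.38 beside these groups.

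Single arrays moved the count of 848 as well: it was 529, 126 and 79 without mock 60 min A, B and C, 151, 238 and 133 without ST 60 min A, B and C, and 1306 and 1362 without mock 120 min A and C. Without the arrays lettered C it was 32, and without these and mock 120 min A it was 84, both chosen after seeing the data, and it was 1957 with array weights and 1330 with trend and robust settings.

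**Figure D2:**
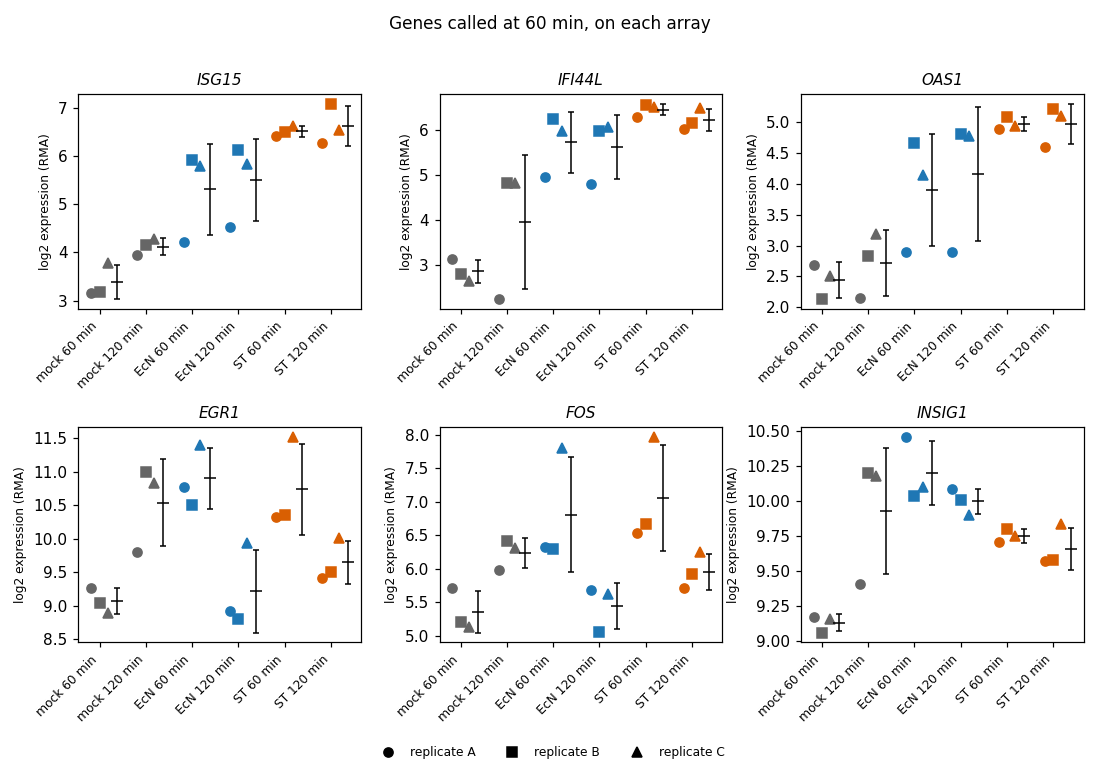
Log2 levels of ISG15, IFI44L, OAS1, EGR1, FOS and INSIG1 by group, with a point per array, a horizontal mark at the mean of 3 arrays and whiskers of 1 SD. ISG15 lies between 3.17 and 3.79 in mock at 60 min, between 4.22 and 5.91 with EcN and between 6.41 and 6.62 with ST.

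The mean of both flagellins at 60 min, 6 arrays against 3, asked for a response common to both. IFI44L rose by 3.23 ± 0.46 (9.35-fold), ISG15 by 2.53 ± 0.35, OAS1 by 1.99 ± 0.40, EGR1 by 1.75 ± 0.32, FOS by 1.58 ± 0.33, GDF15 by 1.07 ± 0.22 and INSIG1 by 0.85 ± 0.15. FOSB, called for neither flagellin alone, rose by 2.32 ± 0.62. GALR2 fell by 1.27 ± 0.19, H2BC12 by 1.15 ± 0.22 and SMAD7 by 0.95 ± 0.18. Of 1657 genes called, 730 were higher and 927 lower, or 600 and 1170 after centring, and 433 changed at least 1.5-fold. Adjusted p was 0.00523 for IFI44L and ISG15, 0.00717 for EGR1 and 0.0058 for GALR2.

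With both flagellins at 60 min, 17 of 20 interferon-stimulated genes rose, 18 adjusted over the list alone (median 1.39, adjusted p = 2.73e-18, adjusted p = 0.133 with an estimated correlation). Of 28 immediate-early genes 8 rose, FOSB and IER2 among them, and 10 adjusted over the list alone (median 0.32, adjusted p = 0.00097, adjusted p = 0.6 with an estimated correlation). GDF15 and TP53I3 made up the 2 of 11 p53 targets called, 3 adjusted over the list alone (median 0.24, adjusted p = 0.0209, adjusted p = 0.133 with an estimated correlation). TRIB3, CEBPB, PHGDH and XBP1 rose in the unfolded protein response list, 4 of 18 and also 4 adjusted over the list alone (median 0.28, adjusted p = 0.0437, adjusted p = 0.6 with an estimated correlation). Other NF-kB targets passed their set test with 1 member called (median 0.35, adjusted p = 0.0383, adjusted p = 0.6 with an estimated correlation). In the TLR5-MyD88 list PELI1 and UNC93B1 rose and MYD88, IKBKG and TIRAP fell. The cell cycle list had 1 gene called, PCNA, which rose by 0.28. In the housekeeping list B2M rose and HPRT1 fell by 0.34. The count of 1657 was 432 and 352 without mock 60 min B and C. Other NF-kB targets lost their call without mock 60 min C, mock 120 min C, EcN 60 min C or ST 60 min C (adjusted p = 0.0691, 0.051, 0.0576 and 0.124). For the unfolded protein response this held without mock 60 min C, mock 120 min B, mock 120 min C, EcN 60 min A or ST 60 min C (adjusted p = 0.158, 0.0545, 0.051, 0.177 and 0.101). The gene count was 243 without the arrays lettered C and 789 without these and mock 120 min A, both chosen after seeing the data, and 2793 with array weights.

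After 120 min 10 genes differed between EcN flagellin and mock, 4 higher and 6 lower, or 24 and 9 after centring and 14 and 8 after renewed quantile normalization. RRS1, a ribosome assembly factor, rose by 1.16 ± 0.20 and RRBP1, a ribosome-binding protein of the endoplasmic reticulum, by 0.94 ± 0.16. FBXO45, a ubiquitin ligase subunit, rose by 0.80 ± 0.13 and UMPS, an enzyme of pyrimidine synthesis, by 0.77 ± 0.13. The retinoic acid receptor RARA fell by 0.77 ± 0.13, INAFM2 by 0.79 ± 0.11 and the ubiquitin ligase RNF138 by 0.95 ± 0.15. FAM221A fell by 0.99 ± 0.15, ENPP5 by 1.00 ± 0.16 and the pseudogene RNA5SP496 by 1.75 ± 0.26. The adjusted p lay between 0.0273 for INAFM2 and 0.0466 for RARA.

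Interferon-stimulated genes lay above mock with EcN at 120 min in all 20 members, and limma called 0 of them, with 13 higher at an unadjusted p under 0.05 and 8 adjusted over the list alone (median 0.74, adjusted p = 3.61e-09, adjusted p = 0.894 with an estimated correlation). OAS2 (1.67 ± 0.38, adjusted p = 0.0757) and ISG15 (1.37 ± 0.41, adjusted p = 0.119) did not pass. Immediate-early genes lay below mock (median -0.33, adjusted p = 0.00423, adjusted p = 0.959 with an estimated correlation), and limma called 0 of 28, with 1 higher and 7 lower at an unadjusted p under 0.05. EGR1 itself, at -1.32 ± 0.37, did not pass (adjusted p = 0.11). Housekeeping genes also lay below mock (median -0.24, adjusted p = 0.0112, adjusted p = 0.894 with an estimated correlation), and limma called 0 of 10, with 0 higher and 6 lower at an unadjusted p under 0.05 and 4 lower adjusted over the list alone. For NF-kB subunits and inhibitors limma called 0 of 20, with 1 higher and 1 lower at an unadjusted p under 0.05 (median -0.12, adjusted p = 0.911). Without mock 120 min A or EcN 120 min B the calls ended for immediate-early genes (adjusted p = 0.09 and 0.19) and for housekeeping genes (adjusted p = 0.0559 and 0.19).

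The count of 10 was 5, 0 and 5 without mock 60 min A, B and C, and 38, 0 and 1177 without mock 120 min A, B and C. It was 5 without EcN 60 min B, 1, 0 and 0 without EcN 120 min A, B and C, 1 without ST 60 min C, and 1 and 0 without ST 120 min A and B. It was 124 without the arrays lettered C, chosen after seeing the data, 214 with trend and robust settings, 37 with the stricter filter, 4 with the letter as a block, and 0 in a fit of the compared groups alone.

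With ST flagellin after 120 min interferon-stimulated genes were higher than in mock: ISG15 rose by 2.50 ± 0.41 (5.66-fold), OAS1 by 2.24 ± 0.46, and OAS2 by 2.15 ± 0.38. The interferon regulatory factor IRF7 rose by 1.42 ± 0.23 and IFI35, a protein induced by interferon, by 1.28 ± 0.23. The dynein gene DNAH17 rose by 1.15 ± 0.16, and the collagenase MMP13 by 0.97 ± 0.16. The ribosome factors RRS1 and GRWD1 rose by 0.95 ± 0.20 and 0.86 ± 0.16, and the endoplasmic reticulum chaperone partner DNAJC3 by 0.84 ± 0.17. FAM72D fell by 1.06 ± 0.19, the matrix proteoglycan gene LUM by 1.00 ± 0.20, and YPEL3 by 0.98 ± 0.18. TMEM47 fell by 0.97 ± 0.20 and TAFAZZIN, which remodels cardiolipin, by 0.84 ± 0.14. Of 90 genes called, 50 were higher and 40 lower, with an adjusted p of 0.0331 for ISG15, OAS2 and IRF7 and of 0.0216 for DNAH17. Of the genes called for ST at 60 min, 24 were also higher and 13 also lower at 120 min, against 1.12 and 1.21 if calls were independent. They are not, since both comparisons use 1 estimate of each gene's spread, so this excess decides nothing.

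Of 20 interferon-stimulated genes 6 rose with ST at 120 min (ISG15, OAS1, OAS2, IRF7, IFI6 and IFIH1), or 16 adjusted over the list alone (median 1.14, adjusted p = 1.71e-16, adjusted p = 0.175 with an estimated correlation). For p53 targets limma called 0 of 11, with 5 higher at an unadjusted p under 0.05 and 2 adjusted over the list alone, and as a list they lay above mock (median 0.21, adjusted p = 0.00243, adjusted p = 0.0463 with an estimated correlation). Heat shock proteins lay above mock (median 0.17, adjusted p = 0.0178, adjusted p = 0.213 with an estimated correlation), and limma called 0 of 7, with 3 higher at an unadjusted p under 0.05 and 3 adjusted over the list alone. TGF-beta and BMP feedback genes did so too (median 0.18, adjusted p = 0.0178, adjusted p = 0.454 with an estimated correlation), and limma called 0 of 11, with 4 higher at an unadjusted p under 0.05 and 4 adjusted over the list alone. Immediate-early genes were near mock (median -0.07, adjusted p = 0.839). For NF-kB subunits and inhibitors limma called 0 of 20, with 2 higher and 1 lower at an unadjusted p under 0.05 (median 0.04, adjusted p = 0.839). Heat shock proteins lost their call without mock 120 min C or ST 120 min C (adjusted p = 0.158 and 0.054), and TGF-beta and BMP feedback genes without ST 120 min A or B (adjusted p = 0.0821 and 0.142). LUM, which fell, was the 1 fibroblast marker called of 3.

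The count of 90 was 905, 0 and 715 without mock 120 min A, B and C, and 0 without ST 120 min A, B or C. It was 59, 1 and 42 without EcN 120 min A, B and C, 39 and 47 without mock 60 min B and C, 46 without EcN 60 min C, and 41, 36 and 42 without ST 60 min A, B and C. The gene count was 0 without the arrays lettered C and 414 without these and mock 120 min A, both chosen after seeing the data, and 298 with trend and robust settings, 169 with array weights, 38 with no filter, 37 with the letter as a random block and 3 in a fit of the compared groups alone.

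With both flagellins together at 120 min ISG15 rose by 1.94 ± 0.35, OAS2 by 1.91 ± 0.33, OAS1 by 1.84 ± 0.40, IFI35 by 1.12 ± 0.20, RRS1 by 1.06 ± 0.17 and IRF7 by 0.96 ± 0.20. The homeobox genes BARHL2 and DLX5 fell by 0.95 ± 0.19 and 0.86 ± 0.14, AJUBA, a scaffold of cell contacts, by 0.79 ± 0.15 and ENPP5 by 0.90 ± 0.14. Of 118 genes called, 68 were higher and 50 lower, or 110 and 48 after centring, with an adjusted p of 0.0278 for ISG15 and 0.0221 for DLX5. Of 20 interferon-stimulated genes 5 rose, 17 adjusted over the list alone (median 0.96, adjusted p = 4.22e-15, adjusted p = 0.315 with an estimated correlation). TGF-beta and BMP feedback genes lay above mock (median 0.23, adjusted p = 0.0281, adjusted p = 0.603 with an estimated correlation), and limma called 0 of 11, with 4 higher at an unadjusted p under 0.05 and 3 adjusted over the list alone. The call of the TGF-beta and BMP list ended without mock 120 min B or C, EcN 120 min A, or ST 120 min A or B (adjusted p = 0.0642, 0.0668, 0.0695, 0.0732 and 0.108). The count of 118 was 549, 0 and 1247 without mock 120 min A, B and C, and 62, 55 and 47 without mock 60 min A, B and C. It was 71, 65 and 54 without EcN 60 min A, B and C, 0 without EcN 120 min B or C, 33 and 61 without ST 60 min B and C, and 34, 29 and 68 without ST 120 min A, B and C. The gene count was 392 without the arrays lettered C and 375 without these and mock 120 min A, both chosen after seeing the data, and 497 with trend and robust settings, 311 with the stricter filter, 52 with the letter as a random block, 45 with no filter and 0 in a fit of the compared groups alone.

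**Figure D3:**
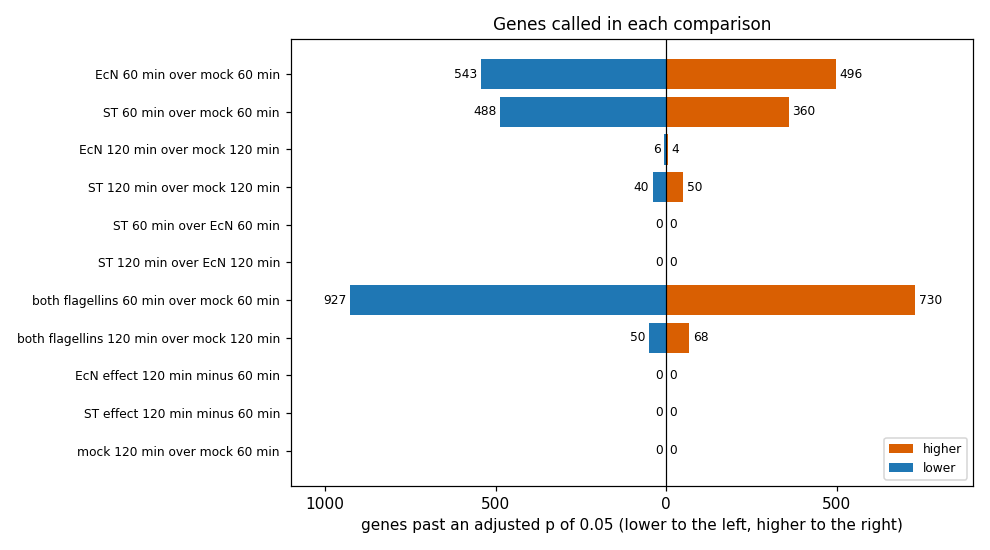
Genes called at an adjusted p under 0.05 in each comparison, with bars for those higher and those lower. Both flagellins at 60 min give 730 higher and 927 lower, and at 120 min 68 and 50.

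ST flagellin was set directly against EcN flagellin at each time. At 60 min limma called 0 genes, with 1481 at an unadjusted p under 0.05 against 806 by chance, and the smallest adjusted p was 0.0729 for the sulfotransferase gene CHST9 (-0.98 ± 0.15). At 120 min limma called 0 genes, with 1882 at an unadjusted p under 0.05, and the haem oxygenase gene HMOX1 (0.86 ± 0.13, adjusted p = 0.0854) and the matricellular gene CCN3 (0.77 ± 0.13, adjusted p = 0.0888) came closest among protein-coding genes. Trend and robust settings called 1 gene at 60 min and 4 at 120 min, and array weights 1 and 34. The 95% interval of the difference, before adjustment for the genes tested, had a median half-width of 0.30 over all genes at each time. This is not a limit of detection, since larger differences such as those of CHST9 and HMOX1 also went uncalled. A count of 0 therefore excludes neither small differences nor many larger ones. For ISG15 the interval ran from 0.35 to 2.06 at 60 min and from 0.27 to 1.99 at 120 min, and for IRF7 from 0.36 to 1.35 and from 0.42 to 1.40, all before adjustment for the genes tested. For CXCL8 it ran from -3.03 to 4.80 at 60 min, so neither a large rise nor a large fall was excluded.

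By list, interferon-stimulated genes lay higher with ST than with EcN at 60 min (median 0.45, adjusted p = 0.000125, adjusted p = 0.525 with an estimated correlation), and limma called 0 of 20, with 5 at an unadjusted p under 0.05 and 1 adjusted over the list alone. They did so at 120 min (median 0.36, adjusted p = 0.00171, adjusted p = 0.699 with an estimated correlation), where limma called 0, with 4 at an unadjusted p under 0.05 and 1 adjusted over the list alone. The p53 targets lay higher with ST at 60 min (median 0.13, adjusted p = 0.0141, adjusted p = 0.173 with an estimated correlation) and at 120 min (median 0.20, adjusted p = 0.00134, adjusted p = 0.0349 with an estimated correlation). Limma called 0 of 11 at either time, with 3 and 4 at an unadjusted p under 0.05 and 1 and 2 adjusted over the list alone. Their sets for ST at 60 and 120 min and for ST over EcN at 120 min were the 3 set tests of 220 that held with an estimated correlation. Heat shock proteins lay higher with ST at 60 min (median 0.24, adjusted p = 0.0316, adjusted p = 0.285 with an estimated correlation) and at 120 min (median 0.20, adjusted p = 0.00134, adjusted p = 0.0662 with an estimated correlation). Cholesterol genes lay lower with ST at 60 min (median -0.22, adjusted p = 0.00609, adjusted p = 0.285 with an estimated correlation) and at 120 min (median -0.19, adjusted p = 0.0133, adjusted p = 0.458 with an estimated correlation). Immediate-early genes lay higher with ST at 60 min (median 0.18, adjusted p = 0.00609, adjusted p = 0.757 with an estimated correlation) and at 120 min (median 0.25, adjusted p = 0.00706, adjusted p = 0.699 with an estimated correlation). At 120 min small nucleolar and related RNAs (median 0.13, adjusted p = 0.00706) and housekeeping genes (median 0.12, adjusted p = 0.0286) were also higher with ST, both with an adjusted p = 0.699 with an estimated correlation.

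The difference between both flagellins in interferon-stimulated genes rested on the arrays EcN 60 min A and EcN 120 min A: the list did not pass without the first (median 0.29, adjusted p = 0.305) or, at 120 min, without the second (median 0.12, adjusted p = 0.426). The p53 targets at 60 min did not pass without EcN 60 min A or ST 60 min B (adjusted p = 0.103 and 0.142). Heat shock proteins at 60 min did not pass without EcN 60 min B or C or ST 60 min B or C (adjusted p = 0.0851, 0.149, 0.0887 and 0.139). Immediate-early genes at 60 min did not pass without EcN 60 min A or B (adjusted p = 0.0515 and 0.135). They turned to a median of -0.02 without ST 60 min C (adjusted p = 0.698). At 120 min immediate-early genes, small nucleolar RNAs and housekeeping genes did not pass without EcN 120 min B (adjusted p = 0.401, 0.23 and 0.401) or ST 120 min C (adjusted p = 0.518, 0.77 and 0.753). Cholesterol genes at 120 min did not pass without EcN 120 min A (adjusted p = 0.0614). Fibroblast markers moved beside these lists: the mean of the 3 measured, too few for a set test, lay between -0.40 and -0.05 on the 6 ST arrays and between 0.03 and 0.28 on the 6 EcN arrays. LUM among them was -0.88 ± 0.20 (adjusted p = 0.252) at 60 min and -0.86 ± 0.20 (adjusted p = 0.16) at 120 min for ST over EcN, and did not pass. At 60 min the count of 0 genes was 1 without EcN 60 min C or ST 60 min A, and at 120 min it was 9 without mock 120 min A and 1 without ST 60 min B. Without the arrays lettered C and mock 120 min A, chosen after seeing the data, the count at 120 min was 1.

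At 60 min the effects of both flagellins went the same way: 171 genes were higher and 248 lower with both. Simulations of unchanged groups that share their mock arrays gave at most 0 shared calls. The test calls almost no gene where nothing is changed, so that comparison decides nothing. The number called in opposite directions was 0. Over the 1468 genes called with either, 99.2% had the same sign, a share that the shared mock arrays favour and that has no simulated background. Across all genes Pearson's r was 0.74 and Spearman's rho 0.71, and genes are not independent replicates. Both comparisons share their mock arrays, which by simulation gave an r of 0.50 and a covariance of 0.017 with no effect, against 0.064 measured. At 120 min 3 genes were higher and 3 lower with both, with r 0.60, rho 0.57 and a covariance of 0.038 against 0.017. With each group's own spread, a background chosen after seeing the data, no effect would give an r of 0.49 and a covariance of 0.014 at 60 min, and an r of 0.61 and a covariance of 0.024 at 120 min, where mock spread most. The r of 0.60 at 120 min was no higher than that background, while the covariance of 0.038 lay above it. The 3 and 3 shared calls decide nothing here, for the reason given at 60 min. The jackknife SD of r was 0.12 at 60 min and 0.24 at 120 min.

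**Figure D4:**
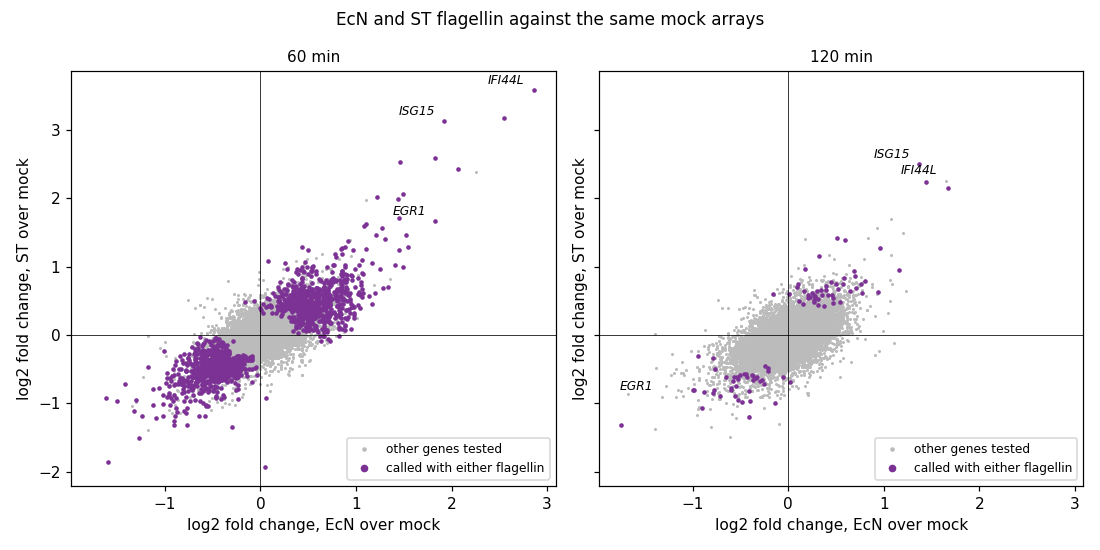
Log2 fold change over mock for EcN (horizontal axis) and ST (vertical axis) at 60 min and at 120 min, with a point per gene and purple for genes called with either flagellin. Pearson's r across all genes was 0.74 at 60 min and 0.60 at 120 min, and groups that share mock arrays with no effect gave 0.50, or 0.49 and 0.61 with each group's own spread.

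Whether the effects changed between 60 and 120 min was tested as an interaction. For EcN limma called 0 genes, with 1936 at an unadjusted p under 0.05, and the effect on EGR1 was lower at 120 min by -3.15 ± 0.53 (adjusted p = 0.169). For ST limma called 0 genes, with 1731 at an unadjusted p under 0.05, and EGR1 and EGR3 had changes of effect of -2.56 and -2.17, both with an adjusted p = 0.31. Immediate-early genes as a list had a lower effect at 120 min with EcN (median -0.52, adjusted p = 1.14e-05, adjusted p = 0.407 with an estimated correlation) and with ST (median -0.45, adjusted p = 5.95e-06, adjusted p = 0.538 with an estimated correlation), and adjusted over the list alone 7 and 8 members were lower. Interferon-stimulated genes did so as well with EcN (median -0.45, adjusted p = 0.0215, adjusted p = 0.565 with an estimated correlation) and ST (median -0.37, adjusted p = 0.0114, adjusted p = 0.56 with an estimated correlation). EGR1 levels were 9.27, 9.04 and 8.89 on mock 60 min A, B and C and 9.80, 10.99 and 10.84 on mock 120 min A, B and C. With EcN they were 10.78, 10.51 and 11.40 at 60 min and 8.92, 8.81 and 9.94 at 120 min, so part of the change of effect lay in mock. For interferon-stimulated genes the list mean rose in mock from -1.02 at 60 min to -0.62 at 120 min. It was 0.22 and 0.19 with EcN and 0.66 and 0.57 with ST. The interferon list lost its call for EcN without mock 60 min B, mock 120 min B or C, EcN 60 min B or C, or EcN 120 min A (adjusted p = 0.0521, 0.0831, 0.134, 0.111, 0.247 and 0.538). For ST it did so without mock 120 min B, ST 60 min C or ST 120 min A (adjusted p = 0.051, 0.0555 and 0.119). Without mock 120 min A the gene counts were 556 for EcN and 475 for ST. Without the arrays lettered C and mock 120 min A, chosen after seeing the data, they were 23 and 1.

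Mock at 120 min against mock at 60 min gave the background of time in culture. Limma called 0 genes, with 1950 at an unadjusted p under 0.05, and INSIG1 (0.80 ± 0.17) and the lysyl oxidase gene LOXL3 (1.04) had an adjusted p of 0.126. EGR1 (1.47 ± 0.37, adjusted p = 0.195) did not pass. Immediate-early genes as a list were higher in mock at 120 min (median 0.36, adjusted p = 1.04e-05, adjusted p = 0.394 with an estimated correlation), with 5 of 28 adjusted over the list alone. Other NF-kB targets (median 0.59, adjusted p = 6.84e-05) and cytokines (median 0.43, adjusted p = 0.000431) were higher too, both with an adjusted p = 0.326 with an estimated correlation, in a group where mock 120 min A stood far above B and C. Array means of other NF-kB targets were 0.72, -0.12 and -0.14 on mock 120 min A, B and C, against -0.44 to -0.34 in mock at 60 min, and those of cytokines 1.00, -0.11 and -0.25, against -0.42 to -0.35. Without mock 120 min A both lists stayed above mock at 60 min and did not pass (median 0.34, adjusted p = 0.0599 and median 0.21, adjusted p = 0.119). Interferon-stimulated genes were higher (median 0.36, adjusted p = 0.00104, adjusted p = 0.507 with an estimated correlation), and IFI44L stood at 2.25, 4.84 and 4.83 on mock 120 min A, B and C against 2.65 to 3.15 in mock at 60 min. The unfolded protein response (median 0.20, adjusted p = 0.0102), cholesterol genes (median 0.12, adjusted p = 0.0197), MAP kinase feedback inhibitors (median 0.06, adjusted p = 0.0209) and small nucleolar and related RNAs (median 0.12, adjusted p = 0.0209) were higher too. TGF-beta and BMP feedback genes were lower (median -0.22, adjusted p = 0.0119). The change of effect subtracts mock, so this fall enters it as a rise. The list mean went from 0.09 at 60 min to -0.14 at 120 min in mock, from -0.12 to 0.04 with EcN and from 0.03 to 0.10 with ST. With an estimated correlation the adjusted p was 0.326 for the cholesterol, MAP kinase and TGF-beta lists and 0.507 for the unfolded protein response and small nucleolar RNAs. Single mock arrays ended each of these 5 calls. The unfolded protein response did not pass without mock 60 min C or mock 120 min B (adjusted p = 0.0697 and 0.0603), nor cholesterol genes without mock 60 min C or mock 120 min B or C (adjusted p = 0.134, 0.0603 and 0.0564). MAP kinase inhibitors did not pass without mock 60 min A or C or mock 120 min A or B (adjusted p = 0.102, 0.0558, 0.119 and 0.0639). The TGF-beta list did not pass without mock 60 min B or C or mock 120 min B (adjusted p = 0.0566, 0.0558 and 0.083), nor small nucleolar RNAs without mock 60 min A or C or mock 120 min A (adjusted p = 0.0578, 0.237 and 0.119). The gene count of 0 was 979 without mock 120 min A, 1 without mock 60 min A and 2 without ST 120 min B. It was 5 without the arrays lettered C and mock 120 min A, chosen after seeing the data.

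The remaining lists held few called genes. Median, mean and test differed in sign for 25 of the 220 list tests, ribosomal proteins with EcN at 60 min among them, none with an adjusted p under 0.699. Of 16 MAP kinase feedback inhibitors SPRED2 fell by 0.56 ± 0.14 with EcN and by 0.55 ± 0.14 with ST at 60 min, and DUSP10 rose with ST, with list medians of 0.11 (adjusted p = 0.212) and 0.20 (adjusted p = 0.0993). For inflammasome genes limma called 0 of 5, with 1 higher and 1 lower at an unadjusted p under 0.05 with EcN at 60 min (median 0.21, adjusted p = 0.532) and 1 higher and 0 lower with ST (median 0.04, adjusted p = 0.669). Among 13 hypoxia genes ENO2 rose by 0.50 with EcN at 60 min (median 0.14, adjusted p = 0.177). For the cell cycle limma called 0 of 15, with 2 higher and 2 lower at an unadjusted p under 0.05 with EcN at 60 min (median -0.03, adjusted p = 0.905) and 1 higher and 4 lower with ST (median -0.09, adjusted p = 0.367). In the TGF-beta and BMP list ID4 rose by 0.61 ± 0.15 with ST at 60 min while SMAD7 fell (adjusted p = 0.858). Of 154 small nucleolar, Cajal and spliceosomal RNAs 10 were higher and 1 lower with EcN at 60 min (median 0.04, adjusted p = 0.208), and 14 were higher and 2 lower with ST (median 0.05, adjusted p = 0.11). Of 335 microRNA precursors 1 was higher and 10 lower with EcN (median -0.07, adjusted p = 0.177), and 3 were higher and 9 lower with ST (median -0.04, adjusted p = 0.56). Ribosomal proteins had RPS6 as the 1 called of 8 with each flagellin at 60 min (median -0.05, adjusted p = 0.937 with EcN and median 0.05, adjusted p = 0.56 with ST), and LGR5 was the 1 called of 6 intestinal markers (median -0.08, adjusted p = 0.532).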

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

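The tests on NF-kB genes, interferon-stimulated genes and the lower counts at 120 min were chosen only after the result was seen. The splits of the samples were planned, and no group had the 4 arrays needed to look for a single array far from the rest.

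NF-kB genes were raised on 5 arrays that cross the labels. The NF-kB list mean of mock 120 min A lay 0.91 (log2) above the highest of the 5 other mock arrays, 5.38 times their range, while 4 of the 6 flagellin arrays of 120 min lay at or below that highest mock array and 2 within their range. The 5 arrays' medians lay at most 0.04 from the median array, which RMA brings about on any arrays, so this decides nothing about a shift of scale before normalization. A response limited to cultures lettered C is excluded for mock 120 min A only if the label of that array is right. For the flagellin arrays it stays open. There the gap of C over the higher of A and B, at least 0.40 in all 4 groups, only restates how the pattern was found. A wrong label on mock 120 min A cannot be told apart from flagellin reaching that flask, and the values argue both ways: its interferon list mean of -1.09 lay within that of mock 60 min (-1.15 to -0.94) and 0.71 below the lowest flagellin array, and its mean r over all genes was 0.991 with mock 60 min and 0.985 with its own group, against at most 0.988 with a flagellin group, which goes with a mock label of 60 min, though interferon means within a flagellin group ranged by up to 0.92 and no biological explanation in the design covers it.

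The interferon list mean was higher on all 12 flagellin arrays than on any mock 60 min array, but mock 120 min C (-0.32) lay above EcN 60 min A (-0.36) and EcN 120 min A (-0.38), with mock 120 min B (-0.44) close to them. By the list of NF-kB subunits and inhibitors, 8 of the 12 lay above every mock 60 min array in the interferon list and not in that one. That list alone does not decide whether the stimulus that raised NF-kB genes was the cause, since the test asked for the same by each NF-kB list. ST 60 min A and B had NF-kB means of -0.22 and -0.25 with interferon means of 0.55 and 0.68. Mock 120 min A had 0.80 with -1.09. The count was 1 by the cytokine list and 0 by other NF-kB targets, so this explanation stays open. By other NF-kB targets the lowest flagellin array (-0.27) lay above the highest mock 60 min array (-0.34). Yet mock 120 min B and C also lay above mock 60 min in both lists, with cytokine means of -0.11 and -0.25 against at most -0.35. A difference between cultures, their amino acid labels or array batches cannot be told apart from flagellin. None of these is given per array. The interferon list mean ranged by up to 0.92 within a group, against 1.46 between flagellin and mock at 60 min. By letter A, B and C it was -0.36, 0.49 and 0.54 with EcN at 60 min and -0.38, 0.42 and 0.53 at 120 min. With ST it was 0.55, 0.68 and 0.74 at 60 min and 0.32, 0.67 and 0.72 at 120 min. A response to flagellin, the biological explanation the design names, also stays open.

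Fewer genes were called at 120 min than at 60 min. A wider spread between the mock 120 min arrays is a candidate explanation: the count for ST at 120 min was 905 without mock 120 min A and that for EcN 1177 without mock 120 min C, while without mock 120 min B limma called 0 for both. A weaker response of interferon-stimulated genes to ST at 120 min stays open, since their change of effect had an adjusted p = 0.56 with an estimated correlation, against 0.0114 with the preset one. Their list mean was 0.66 with ST at 60 min and 0.57 at 120 min. In mock it went from -1.02 to -0.62, so the smaller difference lay more in mock than in ST.

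In other splits of the same arrays, the count for both flagellins at 60 min was reached in 1 of 84 splits, the real one (1657 genes, at most 7 in another). This excludes chance only if the arrays are independent, and whether a letter stands for a separate culture is not given. A difference between cultures or batches that follows the groups is not excluded by it. For both flagellins at 120 min 3 of 84 splits gave at least the 118 genes of the real one, a share under 0.05. Another split called 333, which points to a structure of the arrays other than the groups. The share therefore does not credit the count to the groups, and chance is not excluded here. For the change of effect between times, all 100 splits drawn gave at least the 0 genes called, with up to 1998 for EcN and 1706 for ST, and since any split reaches a count of 0, this says nothing about chance. Those splits exchange labels within each time separately, and a split that keeps 1 time and mirrors the other would turn a difference of effects into their sum. For 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real count and the highest other were 1039 and 0 for EcN at 60 min, 848 and 0 for ST at 60 min, 10 and 3 for EcN at 120 min, and 90 and 6 for ST at 120 min, with 1 of 10 splits as large in each. For ST over EcN they were 0 and 0 at both times, and for mock at 120 over 60 min 0 and 271, with 10 of 10 splits as large in each. Beside these counts of 0, limma gave 1481, 1882 and 1950 genes at an unadjusted p under 0.05.

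The effect of EcN differed between 120 and 60 min by the set test of the interaction for immediate-early genes (median -0.52, adjusted p = 1.14e-05), interferon-stimulated genes (-0.45, 0.0215), other NF-kB targets (-0.41, 0.0215), cytokines (-0.51, 0.0121), cholesterol genes (-0.18, 0.0431), TGF-beta and BMP feedback (0.26, 0.00268) and small nucleolar and related RNAs (-0.25, 0.00268). The effect of ST differed in the same way for immediate-early genes (-0.45, 5.95e-06), interferon-stimulated genes (-0.37, 0.0114), other NF-kB targets (-0.49, 0.021) and TGF-beta and BMP feedback (0.24, 0.0281), and 0 of these 11 lists passed with an estimated correlation. With each array left out in turn, 4 of the 11 kept their call: immediate-early genes for both flagellins, and TGF-beta and BMP feedback and small nucleolar RNAs for EcN. Without mock 120 min A the calls ended for cytokines (0.239) and other NF-kB targets (0.268 for EcN and 0.231 for ST), and TGF-beta and BMP feedback for ST did not pass (0.0545). The interferon list did not pass without EcN 120 min A (0.538) for EcN or without ST 120 min A (0.119) for ST, and cholesterol genes did not pass without mock 60 min C (0.142). Of the 11960 transcript clusters with no gene given, tested apart from the named genes, 43 were called for EcN, 86 for ST and 210 for both flagellins at 60 min, and 1 was called higher with ST than with EcN at 60 min. Of the 1372 with several gene symbols, 53 were called for EcN, 55 for ST and 108 for both at 60 min, and 15 for EcN (4 higher and 11 lower) and 12 for both at 120 min. For ST at 120 min limma called 0 of either kind, with 1015 and 211 at an unadjusted p under 0.05.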

How the results depend on the processing

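Leaving out all arrays lettered C, alone or with mock 120 min A, was chosen only after seeing the data, and the other tests were planned. No named gene that was called changed sign under any setting. Of the named genes called, 0 of 40 for EcN at 60 min, 11 of 40 for ST at 60 min, 18 of 48 for both at 60 min, and 0 of 10, 0 of 25 and 0 of 25 for EcN, ST and both at 120 min stayed called with each array left out in turn. Settings not named for a count below kept it within 1.5 times, and the cause was not tested except where the setting itself takes away arrays or calls.

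With 1 array left out the counts ran from 0 to 1856 for EcN at 60 min, 79 to 1362 for ST at 60 min, 0 to 1177 for EcN at 120 min, 0 to 905 for ST at 120 min, 0 to 1 and 0 to 9 for ST over EcN at 60 and 120 min, 352 to 2273 and 0 to 1247 for both flagellins at 60 and 120 min, 0 to 556 and 0 to 475 for the change of effect of EcN and ST, and 0 to 979 for mock over time. The passing list tests ran from 41 to 65, and the correlation of both flagellins' effects from 0.68 to 0.79 at 60 min and from 0.51 to 0.72 at 120 min. Over the genes called with either alone, a choice that favours large effects, it was 0.89 and 0.90.

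Without the arrays lettered C the counts were 14 (EcN 60 min), 32 (ST 60 min), 124 (EcN 120 min), 0 (ST 120 min), 243 (both 60 min) and 392 (both 120 min). Without these and mock 120 min A they were 494 (EcN 60 min), 84 (ST 60 min), 414 (ST 120 min), 789 (both 60 min), 375 (both 120 min), 1 (ST over EcN 120 min), 23 and 1 (change of effect of EcN and ST) and 5 (mock over time). The NF-kB list at 120 min turned to -0.37 (adjusted p = 0.00525) for ST and -0.46 (adjusted p = 0.00087) for both without the arrays lettered C, and passed at -0.55 (0.000455) for EcN, -0.57 (0.0249) for the EcN change of effect and 0.35 (0.000759) for mock over time. The choice itself fixes these, since it takes away raised flagellin arrays and keeps the raised mock 120 min A, and without that array too the values were -0.02 (adjusted p = 0.912), -0.07 (0.902), -0.12 (0.755), 0.13 (0.591) and -0.08 (0.358). The direction also reversed for immediate-early genes of ST over EcN at 60 min without ST 60 min C, to -0.02 (adjusted p = 0.698), in a leave-one-out range of -0.02 to 0.36.

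Array weights gave 2176 (EcN 60 min), 1957 (ST 60 min), 169 (ST 120 min), 2793 (both 60 min), 1 and 34 (ST over EcN) and 7 (EcN change of effect). Trend and robust settings gave 1330 (ST 60 min), 214 (EcN 120 min), 298 (ST 120 min), 497 (both 120 min), 1 and 4 (ST over EcN) and 1 (mock over time). A minimum of 1.5-fold left 494, 362, 433 and 58 for EcN, ST and both at 60 min and both at 120 min. Centring gave 33 and renewed quantile normalization 22 for EcN at 120 min. No filter on dim rows gave 38 (ST 120 min) and 45 (both 120 min), and the stricter filter, which tests fewer genes, 37 (EcN 120 min) and 311 (both 120 min). A fit of the compared groups alone, with fewer arrays, gave 0 (EcN 120 min), 3 (ST 120 min) and 0 (both 120 min).

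The labels do not pair the arrays by letter across the groups. After removal of group means, all 3 letters correlated above 0.1 in 0 of 15 pairs of groups. Between flagellin groups the values did go by letter, though weakly: 16 of 18 matches were best with the own letter (6 by chance, r from 0.01 to 0.27). In pairs with a mock group they did not, with 3 of 27 (9 by chance, r from -0.24 to 0.11). With the replicate letter as a block the count was 4 for EcN at 120 min and 1 for the EcN change of effect. As a random block, with a consensus correlation of -0.036, the letter gave 37 for ST and 52 for both at 120 min.

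Of the 52 list tests that passed, 20 kept their call with each array left out in turn and 3 passed with an estimated correlation. By fry in 1 direction, which does not compare a list with other genes, 22 of the 220 passed, 11 of them among the 52. Arrays give no depth, so genes above their array's median on fewer than 3 of the 18 arrays were not tested.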

Other observations

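All tests in this part were planned. The p53 list was higher with ST than with EcN flagellin at 120 min (median 0.20, adjusted p = 0.00134). That 1 array decides this call is excluded, since it held with each of the 6 arrays of both groups left out in turn, with a highest adjusted p of 0.00769. TP53I3, CDKN1A and GDF15 had 95% intervals of 0.26 to 0.91, 0.20 to 0.71 and 0.06 to 1.16 for ST minus EcN, before adjustment for the genes tested. The set is small, with 11 measured members, and a p53 response stays a hypothesis.

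Arrays did not gather by group: 8 of 18 lay closest to an array of their own group, mock 120 min A lay closest to mock 60 min B, and mock 120 min C lay closest to EcN 60 min A. Mock 120 min C was in turn the closest array to EcN 60 min A, B and C and to EcN 120 min A, with a mean r of 0.993 with EcN 60 min and 0.987 with its own group, and without it the count for EcN at 120 min was 1177. Its label was not tested. The first principal component held 21.5% and the second 15.2% of the variance. Correlations between arrays lay between 0.981 and 0.994. The median SD per gene was 0.194 among the mock 120 min arrays and 0.131 to 0.143 in the other groups.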
